A study of Homo sapiens with 2 samples.

How the data were processed

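Libraries were made with a stranded mRNA kit from total RNA of MDA-MB-231 cells, per the labels' protocols: 1 from cells with a short hairpin against CDK14 and 1 from cells with a scramble control. The authors deposited 1 table of RPKM values with 29452 gene rows, giving the exon positions and summed exon length of each row, per the file headers. The submitters' processing notes name Bowtie 0.12.2, featureCounts, Subread 1.5.1 and the builds GRCh38 and mm8, without saying what each was used for. Rows matched GENCODE v29 on GRCh38 for 21045 names with overlapping coordinates, 19841 of them with the same start and end, so coordinates are given on GRCh38. Strand, overlap and multi-mapping options are not given in the sources used here. Exons of 11992 rows overlap another row, and reads of such rows, antisense ones included, cannot be told apart here. In 109 rows the exons lie on more than 1 chromosome. Names of 27 rows read as calendar dates, as spreadsheet software makes of some gene symbols, and these rows were not named.

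The deposited RPKM times length was a whole multiple of a single step per library for 100% of nonzero values, within 0.01 read, so reads per gene were recovered. The recovered reads summed to 15478156 in CDK14-sh and 17217564 in the scramble control, equal to the denominators of the RPKM values. In a gene of 1 kb, 3 reads correspond to 0.194 and 0.174 RPKM. RPKM stayed the main value and reads served for the 95% Clopper-Pearson counting intervals. PCR copies are not independent molecules, so the intervals cover counting error only.

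Ratios were log2((RPKM CDK14-sh + 0.1)/(RPKM scramble + 0.1)), a scale that understates the change of low genes, over genes with RPKM of at least 1 in the higher library. A gene was counted as higher or lower from 2-fold. With 1 library per group no gene was tested for a difference between the groups, and the random lists and permutations used here compare genes with each other. Before the data were examined, 41 gene lists with 1042 distinct symbols were fixed. Each list with at least 5 measured members was set against 10000 random lists of its size, matched on mean level in 20 bins. This describes these 2 libraries. Lists of markers for fibroblasts (2 measured members), leukocytes (2), endothelium (3) and HEK293 or HeLa cells (1) were too small to score.

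Genes were named by a rule also fixed before the data were examined: CDK14 and its measured relatives, the 10 largest ratios in each direction, and up to 4 members of each described list with the largest ratio. The 10 largest were taken among genes with RPKM of at least 5 and 30 reads in the higher library and above 0 in both. The file gives no gene type, so the rule took all named rows, those without a matched gene type included. Genes listed at 0 in a library got no fold. The rule also took 1 gene that is not reported here. Gene types and 3' UTR sequences came from GENCODE v29, using for each gene the basic transcript with the longest 3' UTR.

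On reads simulated for this comparison, all of 50 genes simulated at 2.5-fold (100%) passed 2-fold in the right direction and 0 of 50 at 1.5-fold did. Counting intervals held the simulated ratio for 94% to 98% of genes at each fold size. Of 10 words planted in 3' UTRs at -0.25 log2, 10 were recovered as the lowest. The simulated reads held counting noise only, with no spread between cultures, so these results hold for that noise alone. Alternatives covered the pseudocount, the level filter, the scaling, the size threshold and the random lists. A further 6, covering protein-coding genes, a read minimum, reads scaled to library totals, mitochondrial reads, gene length together with level, and overlapping rows, were chosen after seeing the data. Of the scaling settings, median centring and trimmed-mean scaling could not change a list's place, since they shift every ratio by the same amount. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.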

Results

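RNA sequencing was carried out on MDA-MB-231 cells, an established triple-negative human breast cancer line, after knockdown of CDK14 by a short hairpin RNA (CDK14-sh) and in a scramble control. CDK14 is a cyclin-dependent kinase that pairs with cyclin Y and phosphorylates the Wnt co-receptor LRP6. Each group held 1 library, so no difference below has a replicate check and no p-value is given. The CDK14-sh library held 15478156 reads assigned to genes and the scramble library 17217564. Intervals in parentheses are 95% Clopper-Pearson counting intervals, which cover counting error only, and folds are ratios of RPKM between these 2 libraries. Whether a gene passed 2-fold was decided on the ratio with 0.1 RPKM added to each level. Words such as higher and lower describe these libraries, not the conditions in general.

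The first comparison asks whether the targeted transcript was lower in the library labelled CDK14-sh. CDK14, on chromosome 7 from 90466424 to 91210590 on the plus strand (GRCh38), stood at 0.548 RPKM in CDK14-sh (58 reads) and 2.48 RPKM in the scramble control (292 reads). The level was 22.1% of the control (16.4% to 29.4%), which is 4.53-fold lower (3.40 to 6.11). Among the 10617 protein-coding genes with at least 30 reads in the higher library, CDK14 ranked 11 from the lowest ratio. Exons of the CDK14 row overlap other annotated rows, among them CLDN12, so reads in the shared exons cannot be assigned to CDK14 alone.

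The measured relatives of CDK14 and its cyclin partners stayed within 2-fold. CDK15 and CDK18, which stand in the same list, were not among the genes passing the level filter. CDK17 was 1.47-fold higher (1.34 to 1.62), CDK5 1.27-fold higher (1.03 to 1.55), and CCND3 and CCNY, which encode cyclins D3 and Y, were 1.23-fold and 1.21-fold higher. CDK16 was 1.38-fold lower and CCNYL1, encoding a cyclin Y-like protein, was 1.33-fold lower. Of the 7 measured members, CDK14 alone passed 2-fold.

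The second comparison asks which other transcripts differed in level between the knockdown and the control. Cytokine genes led the transcripts that were higher in CDK14-sh: IL1B, encoding interleukin-1 beta, was 5.85-fold higher (5.27 to 6.51) and IL1A 5.32-fold higher (4.16 to 6.88). CSF3, encoding granulocyte colony-stimulating factor, was 4.14-fold higher (3.75 to 4.58), and the chemokine gene CXCL3 2.76-fold higher (2.43 to 3.14). VNN1, encoding a pantetheinase, was 3.06-fold higher (2.46 to 3.83), and HSD17B10, encoding a mitochondrial dehydrogenase, was 2.78-fold higher (2.40 to 3.22). Another 3 of the 10 largest ratios in this direction belonged to short rows with few reads and no matched gene type: SNORA24 (64 against 18 reads), AC113188.2 (45 against 17) and RP5-862P8.3 (34 against 13). They overlap the rows of SNHG8, SAMD12 and PCNX2, in that order, and the SNORA24 row joins exons on more than 1 chromosome, so its reads belong to no single locus.

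Lower in CDK14-sh were UBL3, encoding a ubiquitin-like protein, by 6.37-fold (5.11 to 8.01), and SFN, encoding 14-3-3 sigma, by 4.38-fold (3.71 to 5.20). TLN1, encoding talin 1, which couples integrins to actin, was 4.30-fold lower (4.09 to 4.51). AIDA was 4.18-fold lower (3.80 to 4.60) and STARD3NL 4.06-fold lower (3.55 to 4.65). CD55, encoding a complement regulator of the cell surface, was 3.94-fold lower (3.61 to 4.30), FAM83D 3.93-fold lower (3.32 to 4.68) and RCSD1 3.92-fold lower (3.43 to 4.50). SUPT16H, encoding a subunit of the histone chaperone FACT, was 3.72-fold lower (3.54 to 3.90). RNA5SP352, a 5S ribosomal RNA pseudogene row that overlaps SIAE, had 5 reads in CDK14-sh and 75 in the control. MIR361 (6 reads) and MIR6079 (5 reads) were listed at 0 in the scramble control.

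**Figure D1:**
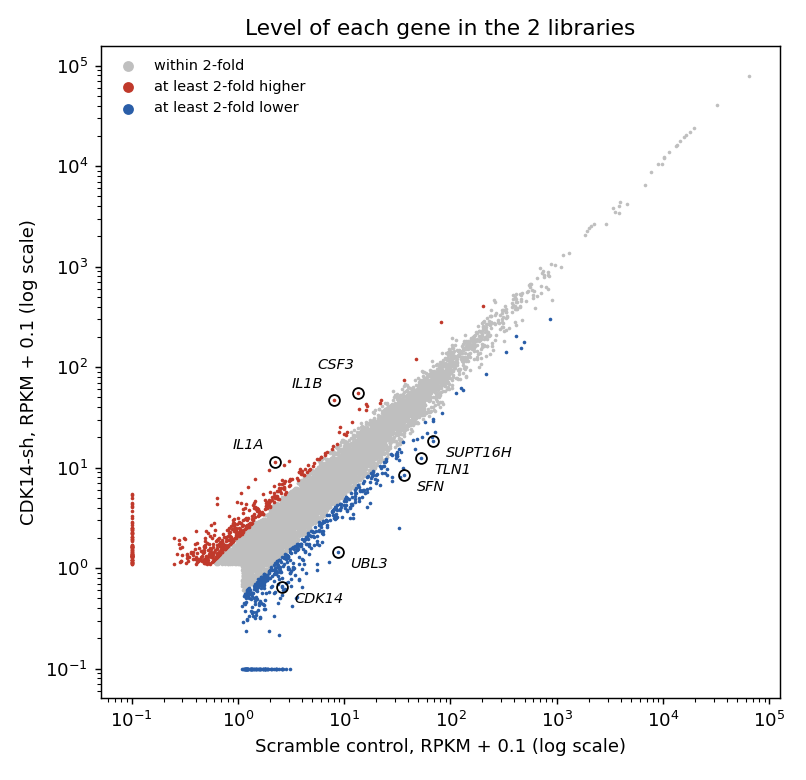
Level of each of the 14878 genes passing the level filter in the scramble control (x axis) and the CDK14-sh library (y axis), as RPKM + 0.1 on log scales, with genes at least 2-fold higher in red and lower in blue. Genes listed at 0 in a library lie at 0.1 on its axis, and 93.3% of genes lie within 2-fold.

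**Figure D2:**
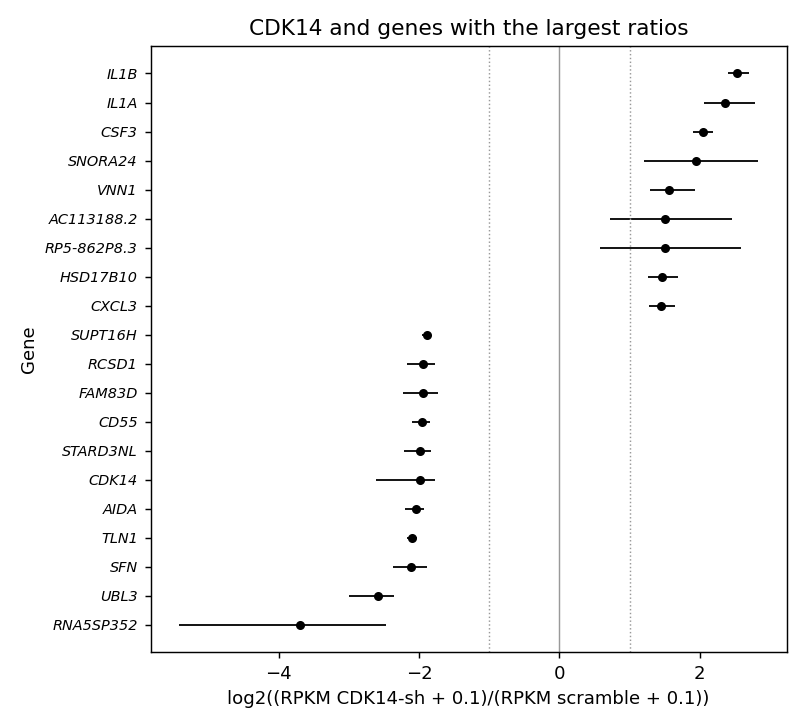
Log2 ratio of CDK14-sh over scramble control, with 0.1 RPKM added to each level, for CDK14 and genes from the 10 largest ratios in each direction under the fixed rule (points); bars are 95% counting intervals of the reads without that addition. Dotted lines mark 2-fold, and the widest bars belong to rows with few reads, such as RNA5SP352.

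Of the 14878 genes with at least 1 RPKM in the higher library, 478 were at least 2-fold higher and 516 at least 2-fold lower in CDK14-sh, so that 51.9% of these were lower. The direction of this excess depended on the setting: with mitochondrial reads left out of the totals, 622 were higher and 536 lower, and with no level filter 2173 and 2043. Rescaling each library to a common sum of RPKM (TPM) gave 609 higher and 1128 lower. It changes the scale between the libraries by -0.15 log2, and also which genes pass the level filter and how much the added 0.1 weighs. Counting noise alone, simulated from a shared level per gene, gave a mean of 184 higher and 166 lower genes. Most of the higher genes (312) had fewer than 30 reads in the higher library. Among the 10668 genes that GENCODE v29 lists as protein-coding, 111 were higher and 230 lower, against 2.48 and 2.08 from counting noise alone.

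Many of the lower protein-coding genes shared short words in their 3' untranslated regions (UTRs). At least 1 of the 7-base words GTCATGC, TCATGCA, ATCCATA and TCCATAA, which were picked from these same ratios, occurred in 129 of 225 lower genes searched (57.3%). It occurred in 24.6% of genes within 2-fold and 16.7% of the 102 higher genes searched. These shares were not matched on 3' UTR length. Of the named genes above, UBL3, SFN, TLN1, FAM83D and SUPT16H carried GTCATGC, AIDA carried ATCCATA and STARD3NL carried TCATGCA, while CD55 and RCSD1 carried none.

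**Figure D3:**
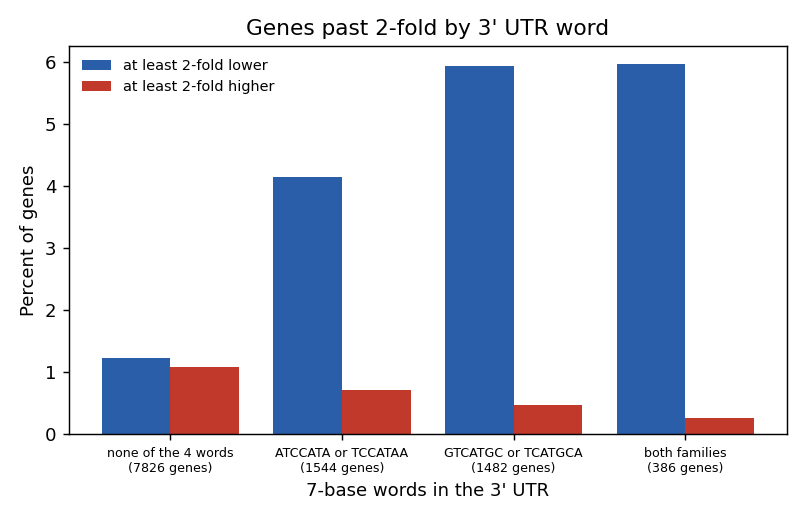
Percent of protein-coding genes at least 2-fold lower (blue) or higher (red) in CDK14-sh, by 7-base words in the 3' UTR; the groups of the 2 word families overlap, and genes with both stand in the last group too. Of genes with none of the 4 words, 1.23% were lower and 1.09% higher, against 5.94% and 0.47% of genes with GTCATGC or TCATGCA.

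Of the 37 fixed gene lists with at least 5 measured members, 4 had a median ratio above and 8 below the central 95% of random lists matched on level. If genes and lists were independent, 1.85 would fall outside by chance. Lists share members and genes of a list can vary together between any 2 cultures, so that number is not an expectation for real lists. NF-kB targets and cytokines stood highest, with a median log2 ratio of 0.54: 8 of 26 measured members were at least 2-fold higher and 0 lower, and IL1B, IL1A, CSF3 and CXCL3 had the largest ratios. The ribosomal protein list had a median of 0.27, with 59 of 61 members above 0 and RPL15 1.53-fold higher and RPS12 1.52-fold higher, while RPL37 was 1.59-fold lower. Nuclear-encoded oxidative phosphorylation genes had a median of 0.26, with 41 of 45 above 0. COX5B was 1.53-fold and COX7B 1.51-fold higher, and SDHD, encoding a succinate dehydrogenase subunit, 2.76-fold lower. SDHD and RPL37 carry the 3' UTR word GTCATGC, while RPL15, which was higher, carries TCATGCA and TCCATAA. Mitochondrially encoded genes had a median of 0.25, at percentile 97.8, and took 17.1% of reads in CDK14-sh against 14.5% in the control. Their place outside the random lists was lost in 5 of 14 alternative settings. In TPM the medians of the ribosomal, oxidative phosphorylation and mitochondrially encoded lists were smaller, 0.12, 0.11 and 0.09, and above the random lists. The change of scale in TPM lowers the random lists too, so this is little of a check. Random lists were not matched on transcript length, and the shortest of 4 equal groups of protein-coding transcripts had a median of 0.13. The correction for gene length used summed exon length, so the part of transcript length in these medians stays open.

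Among integrins and focal adhesion genes the median log2 ratio was -0.40, and 4 of 24 members were at least 2-fold lower: TLN1, ITGB1 (2.31-fold), ITGA1 (2.24-fold) and ITGB4 (2.02-fold). TLN1 and ITGA1 carry a 3' UTR word from those above, while ITGB1 and ITGB4 do not. Without the genes that carry one the median was -0.29, still below the random lists. The actin cytoskeleton list had a median of -0.19 with 18 of 26 members below 0, and ACTG1, encoding gamma actin, was 1.75-fold lower and FLNA, encoding filamin A, 1.49-fold lower. Over rows overlapping no other, the median of this list was -0.11 and lay within the random lists. YAP/TAZ targets had a median of -0.29, and 3 of 23 passed 2-fold: ANKRD1 (2.73-fold lower), IGFBP3 (2.58-fold) and AJUBA (2.32-fold). The median was -0.13 after a correction for gene length and level together, still below the random lists, and -0.08, within them, without the genes that carry a 3' UTR word. AJUBA carries one, and leaving such genes out favours higher medians, since the words were picked from these same ratios. In the G2/M list, 33 of 35 members lay below 0, with a median of -0.36. KIF23, encoding a kinesin of the central spindle, was 2.33-fold lower, and CCNB2 (cyclin B2) 1.65-fold and TTK 1.64-fold lower.

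Mammary stem cell and stemness genes had a median of -0.57, with ID4 3.72-fold lower, ID1 2.37-fold lower and ITGB1 again among them. The list went both ways, with 7 of 12 measured members below 0 and 5 above, and its mean was -0.40. With no level filter this median was 0.075. Luminal breast epithelium markers had a median of -0.47, and SPDEF, encoding an epithelial ETS transcription factor, was 3.54-fold lower. With no level filter this median was -0.15 and lay within the random lists. Epithelial junction and keratin genes had a median of -0.23, with KRT19 1.82-fold and KRT8 1.76-fold lower, a place outside the random lists that was lost in 7 of 15 alternative settings. KRT8, KRT18 and KRT19 stand in the luminal list too, so the 2 lists are not separate results, and the KRT8 and KRT18 rows overlap. The heat shock list had a median of -0.15, with CHORDC1, which carries a 3' UTR word, 1.74-fold lower. This list stayed below the random lists in 12 of 15 alternative settings. Median centring and trimmed-mean scaling, which could not change its place, are counted in that number.

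**Figure D4:**
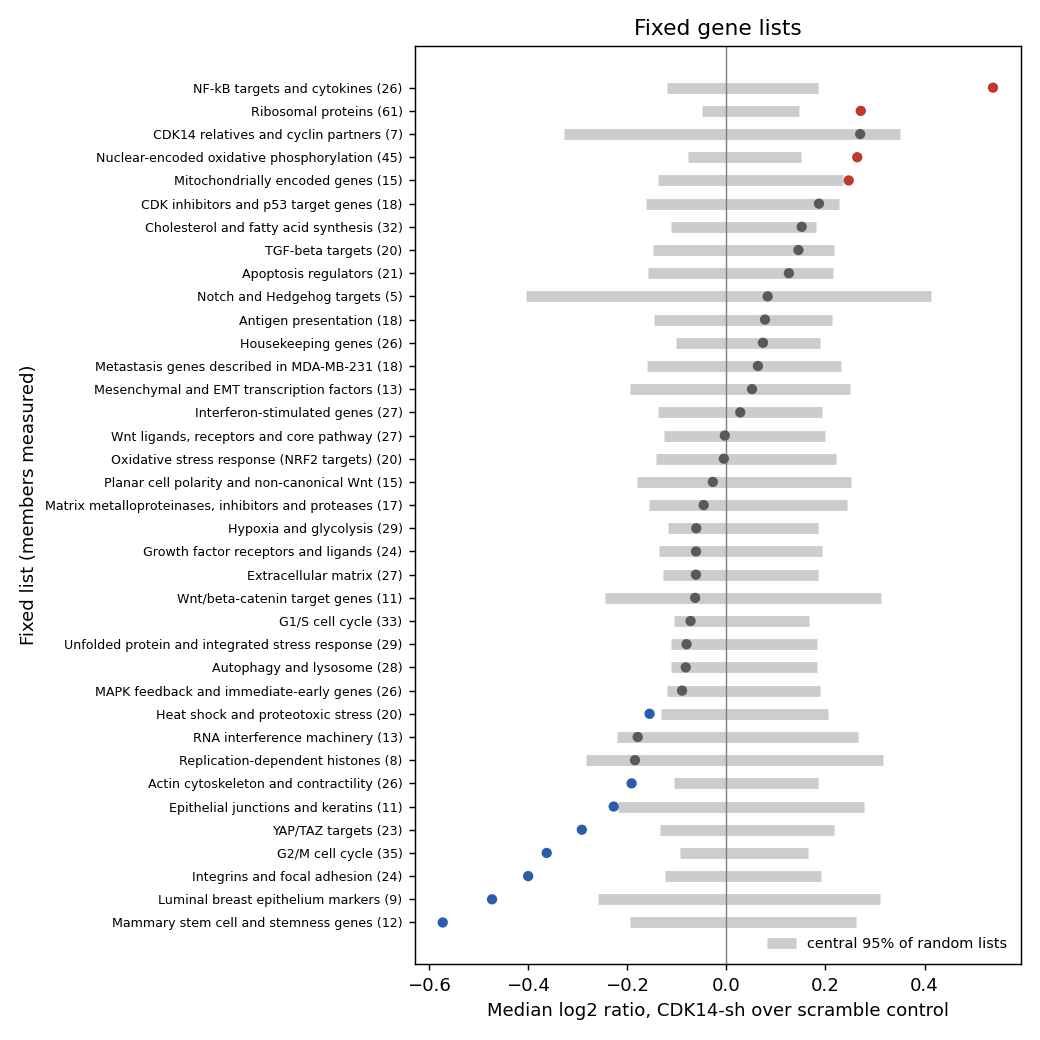
Median log2 ratio of CDK14-sh over scramble control for each of the 37 scored lists (points, with the number of measured members) and the central 95% of 10000 random lists matched on level (grey bars). Red points lie above and blue points below the bars, from 0.54 for NF-kB targets to -0.57 for mammary stem cell genes.

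CDK14 acts in Wnt signalling, and lists of that pathway lay within the random lists with the settings used throughout. Wnt/beta-catenin target genes had a median of -0.06 over 11 members, and their place changed in both directions with the setting. They lay below the random lists with no level filter (median -0.27), in TPM (-0.41) and with reads scaled to library totals without length (-0.30), and above them with at least 5 RPKM required (0.59) and over rows overlapping no other (0.48). The level filter and the choice of rows change which genes enter and not their ratios, so those medians rest on sets other than these 11. Which members made the difference was not tested. AXIN2, a feedback inhibitor of the pathway, was 2.99-fold lower (1.94 to 4.73), BMP4 2.26-fold lower and LEF1 1.82-fold lower, while FOSL1 was 1.69-fold higher. AXIN2 and LEF1 carry 3' UTR words from the 4 above, and without the genes that carry one the median was 0.36 and lay above the random lists. The words were picked from these same ratios, so leaving out their carriers favours a higher median. Wnt ligands, receptors and core components had a median of -0.003, with WNT7B 2.20-fold lower, and planar cell polarity genes a median of -0.03. Mesenchymal genes had a median of 0.05, with MSN (moesin) 2.56-fold lower and VIM (vimentin) 1.70-fold lower. With at least 5 RPKM required that median was -0.33, below the random lists, and in TPM it was -0.10, within them. MSN and VIM carry a 3' UTR word too, as do 7 of the 13 measured mesenchymal genes in all. CDK inhibitors and p53 targets had a median of 0.19, within the random lists, though by their mean of 0.24 they lay above them. CDKN1A, encoding p21, was 2.05-fold higher.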

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

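No paired analysis was possible because each group held 1 library, and no gene was tested for a difference between the groups. Of 16 alternatives, 6 were chosen after seeing the data: protein-coding genes, the read minimum, reads scaled to library totals, mitochondrial reads left out, the correction for length and level and rows overlapping no other. Genes at least 2-fold higher and lower numbered 478 and 516, and the counts moved with the rule: 176 and 259 with a pseudocount of 1 RPKM, 2173 and 2043 with no level filter, 83 and 177 with at least 5 RPKM, and 1355 and 1421 at 1.5-fold. They were 111 and 230 among protein-coding genes, 166 and 290 with at least 30 reads, and 307 and 315 over rows overlapping no other, where fewer genes entered. TPM gave 609 and 1128, and leaving mitochondrial reads out of the totals 622 and 536. The log2 ratio of CDK14 was -1.99, and -1.17 with a pseudocount of 1 RPKM, which weighs more on a gene at this level; it had no value with at least 5 RPKM or over rows overlapping no other. Lists below the random ones numbered 8, and 5 with no level filter, which changes the genes that enter and not their ratios. Which genes made the difference was not tested. Lists above numbered 3 or 4 in each alternative, though not always the same ones. With at least 5 RPKM, Wnt/beta-catenin targets lay above and mitochondrially encoded genes within. By the mean of each list, CDK inhibitors and p53 targets lay above and mitochondrially encoded genes again within. Median centring and trimmed-mean scaling shift every ratio by the same amount, so list calls could not change under them. Of 549 list calls in alternatives, these settings included, 520 were unchanged, 17 fell within the random lists and 7 moved outside them. The other 5 changed sign and lost or gained a place outside the random lists. Wnt/beta-catenin targets stood at 0.59 with at least 5 RPKM and at 0.48 over rows overlapping no other. Mesenchymal genes stood at -0.33 with at least 5 RPKM, and stemness genes at 0.075 with no level filter. Metastasis genes stood at -0.27 over rows overlapping no other. These settings keep every ratio and change only which genes enter. Which members made the difference was not tested. Among the 520 unchanged calls, 38 values also had the opposite sign, with the list within the random ones in both settings. Of 2006 values of named genes in alternatives, 1830 stayed within their counting interval, 176 moved and 0 of those called at 2-fold changed sign. Settings based on gene types or counts given by the authors were not run, since the columns used hold neither.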

Other observations

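Some fixed lists not described above held members past 2-fold while their medians lay within the random lists. In the cholesterol and fatty acid list (median log2 ratio 0.15), INSIG1, which retains the SREBP activator in the endoplasmic reticulum, was 2.96-fold lower and SC5D 2.23-fold lower, while SCD was 1.82-fold higher. Among matrix proteases and inhibitors (median -0.05), PLAU, encoding urokinase, was 2.56-fold higher and ADAMTS1 2.15-fold lower; PLAU shares exons with C10orf55. In the extracellular matrix list (median -0.06), SPOCK1 was 2.97-fold higher and HSPG2, encoding perlecan, 2.33-fold lower. TGF-beta targets (median 0.15) held PMEPA1 (2.04-fold higher) beside ID1. MCM3 was 2.35-fold lower in the G1/S list (median -0.07), SLC7A5 2.54-fold lower in the stress response list (median -0.08), MITF 2.38-fold lower in the lysosome list (median -0.08), SPRY1 2.60-fold lower in the MAPK list (median -0.09) and IGFBP4 2.02-fold lower in the growth factor list (median -0.06). Some of these places or medians changed with the setting. The MAPK list lay below the random lists over rows overlapping no other (-0.28) and after the correction for length and level (-0.10). Its median was 0.07, within them, with no level filter. The growth factor list lay below the random lists by its mean (-0.19). The median of TGF-beta targets was -0.06 in TPM, which changes the scale, and stayed within them. BIK, a pro-apoptotic gene, had 33 reads in CDK14-sh and 5 in the control, in the apoptosis list (median 0.13).

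No member passed 2-fold among interferon-stimulated genes (27 measured, median 0.03), antigen presentation genes (18, median 0.08), hypoxia and glycolysis genes (29, median -0.06), RNA interference genes (13, median -0.18), Notch and Hedgehog targets (5, median 0.08), histones (8, median -0.18) or housekeeping genes (26, median 0.07, and -0.08 in TPM). Nor did any of the NRF2 targets (20, median -0.005) with 0.1 RPKM added to each level, though HMOX1 was 2.20-fold lower (1.24 to 4.04) as a plain ratio of RPKM. Metastasis genes described in this line had a median of 0.06 (-0.22 in TPM, and -0.27, below the random lists, over rows overlapping no other) and went both ways, with CXCL1 2.01-fold higher and ID1 lower. The few measured markers of other cell types were COL1A1 and COL6A3 for fibroblasts, LAPTM5 and CD68 for leukocytes, ESAM, ROBO4 and KDR for endothelium, and ZIC2, with ratios between -0.72 and 0.26 log2.

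The tests below were set down before their results were seen, except those on scaling, counting error, single cultures and genes with none of the 4 words, the last chosen after the share of genes with each word was seen. More protein-coding genes were lower than higher in CDK14-sh, 230 against 111. Removing the trend on transcript length, GC and level left 2.40 lower genes for each higher one, which argues against that trend as the whole cause. Length did go with the ratio: the median log2 ratio was 0.13 in the shortest of 4 equal groups of transcripts and -0.05 in the longest. In the shortest group fewer genes were lower than higher, 41 against 54, while the longest had 69 against 17. Centring on the median ratio gave 2.55 lower genes for each higher one, but this median was above 0 (0.039), so centring could not lower that number and the part of scaling stays open.

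A candidate explanation is an off-target effect through the seed of a small RNA, which pairs with short words in 3' UTRs. Of all 16384 words of 7 bases, GTCATGC went with the lowest ratios (z of -15.33, against a lowest of -5.51 in 100 permutations), and 62 of 225 lower genes carried it (27.6%, against 5.98% of genes within 2-fold). The words of a second family, ATCCATA and TCCATAA, had z of -11.16 and -8.95. In genes with none of the 4 words, lower genes numbered 1.13 for each higher one, 96 against 85. The excess of lower genes may lie in the genes with a word, but these counts cannot settle it. The words were picked from the same ratios, which favours this outcome. The z were corrected for 3' UTR length, GC and level, while the counts were not matched on length. Longer 3' UTRs have more places for a word, and the shortest transcripts held 41 lower genes against 54 higher ones.

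Whether the words come from the hairpin stays open, since its sequence is not given in the sources used here. If both families came from the strands of 1 hairpin against CDK14, its transcript should hold GTCATGC with TATGGAT 6 to 20 bases before it, and 0 such pairs were found. That test covered 1 strand assignment. The other, ATCCATA with GCATGAC before it, was added after this result and also gave 0 pairs. Neither assignment was borne out in the 4995-base transcript searched. Taken singly, that transcript held GTCATGC 0 times, TATGGAT 1 time, ATCCATA 1 time and GCATGAC 2 times, and its 3' UTR held 0 of the 4 words. A hairpin against CDK14 acting through 1 word family only was not tested. Hairpins aimed elsewhere, a small RNA that differs between the cultures, and other CDK14 transcripts may still be the source and were not tested. Without the genes that carry a word, 6 of the 8 lists below the random ones and 3 of the 4 above them kept their place. YAP/TAZ targets and heat shock genes fell within, each with a median of -0.08. Mitochondrially encoded genes held no word and their median stayed at 0.25, but against the new random lists it lay within, at percentile 97.1. Wnt/beta-catenin targets lay above, with a median of 0.36 over 9 members. The words were picked from the same ratios, so leaving out their carriers favours higher medians in each of these lists.

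IL1B, IL1A, CSF3 and CXCL3 were higher in CDK14-sh together with LIF (log2 ratio 1.30) and IL6 (1.19), which were named after their values were seen. Leukocytes in the culture are argued against: of the 5 marker genes set down beforehand, TYROBP had no row, and the sum of PTPRC, CD53, LAPTM5 and LYZ changed by -4.43% of the rise of IL1B. LAPTM5 made up most of that sum in both libraries, and without it the change was 0.35%. Of the 6 counting intervals 0 reached 0, and the lowest bound was 0.91. The genes were picked for their large ratios, so this outcome followed from the choice and is no independent test of counting error. With 1 library per group, an effect of CDK14, an off-target effect of the hairpin and a difference between single cultures cannot be told apart, and no biological explanation was tested.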
